A study of Homo sapiens with 3 samples.

How the data were processed

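RNA was sequenced from 3 cultures of MDA-MB-231, a human triple-negative breast cancer cell line, 1 library per group. The groups were a control, a FoxO3 depletion and a co-depletion of Geminin and FoxO3. Per the labels' protocols, cells were infected with lentivirus, given fresh medium and harvested later, and libraries were made from total RNA with an Illumina TruSeq RNA kit. Each library's group was taken from its title read with the series' design text. The titles of both depleted libraries end in a number that the control's title lacks, and the labels do not explain it. The sequence used for depletion is not given in the sources used here, nor is the vector of the control.

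The deposited files hold FPKM (fragments per kilobase of transcript, scaled to library size) per Ensembl gene, 1 file per library, with 48162 genes in each. The submitters' processing notes name TopHat2 2.0.9. The read counter, genome build, annotation, FPKM tool and strand setting are not given in the sources used here. Reads of overlapping genes, antisense partners and near-identical copies therefore cannot be told apart, and such genes are described as uncertain. No coordinates are given for the same reason. Gene names, gene classes, transcript lengths and GC content came from GENCODE 29, which matched 45342 of the 48162 gene IDs.

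FPKM values hide the read depth, so it was sought in the values. A gene's FPKM in each library is a whole number of reads times a step, and the steps of different libraries stand in 1 ratio for all genes. That ratio was found from low genes, and the smallest set of whole reads was then searched for each gene up to 60000 reads. Whole reads were found for 97.0% of the 20591 genes above 0 in at least 2 libraries, against 0.05% of 2000 random values. Relative to the control, depth was 74.2% in the FoxO3-depleted library and 84.6% in the co-depleted library. Among 2447 genes with a single GENCODE 29 transcript, 1658 gave the same total to within a relative tolerance of 1e-06, which puts the total behind the FPKM values at 14507410 reads for the control, 10760613 for the FoxO3 depletion and 12267332 for the co-depletion. The commonest product of FPKM and length within each library, which uses no other library, gave the same 3 totals. Of 12169 genes with 3 or more transcripts, the length implied by the FPKM lay within 0.5 bases of the mean transcript length for 30.6%, and of the longest for 0.16%. Levels of different genes within a library therefore depend on that length, while ratios between libraries do not.

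Recovered reads can be the true reads divided by a common factor, so intervals computed from them can be wider than the true ones. Intervals of FPKM ratios are exact 95% Clopper-Pearson intervals on the reads of 2 libraries. They cover counting error only, compare those libraries and not the conditions, and say nothing of variation between cultures.

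Ratios were taken as log2 of (FPKM + 1) in the first library over (FPKM + 1) in the second, which understates differences of low genes. The 12649 genes with a GENCODE 29 name and a mean FPKM of at least 1 over the 3 libraries were analysed, 11435 of them protein-coding. A further 297 genes above that mean have no name in GENCODE 29 and were not used here. With 1 library per group no difference has a replicate check, and no p-value was computed. A gene was called higher or lower by size alone, at 2-fold on the FPKM + 1 scale.

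Before the data were examined, 41 gene lists were fixed. Some genes belong to more than 1 list, so the lists are not separate pieces of evidence. Members were counted at 1.5-fold. For lists with at least 5 measured members, the median log2 ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. A list is said to stand apart when its median lies outside the central 95% of the random medians. By chance 5% of lists of unrelated genes do so in each comparison. Lists whose genes vary together can do so more often, at a rate that was not measured. Named genes followed a rule fixed at the same time. It takes FOXO3, GMNN and DICER1, the 12 highest and 12 lowest ratios per comparison, up to 4 members of each list with the largest ratios, and 8 genes per direction shared by both depletions. A few members of the lists are not analysed here because their IDs had no match.

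Both comparisons with the control use the same library, so their agreement was set beside 100 simulations of 3 exchangeable libraries, with the spread of each expression level taken from the 3 real ones. The alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, a mean of at least 5 FPKM, no minimum, rescaling by the median ratio of genes or to TPM, size rules of 1.5-fold and 3-fold, and protein-coding genes alone. Chosen after seeing the data were an adjustment for GC content (the running median ratio over 50 bins of GC subtracted), the same for GC and length, and a minimum of 20 recovered reads.

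The methods were tested on simulated data for the comparison of FoxO3 depletion with control, using read counts drawn at the real means, lengths and depths for 24822 genes, with 200 genes altered. Of genes altered 2-fold, 28.4% passed the size rule in the right direction, as did 86.4% of those altered 3-fold and 91.0% of those altered 4-fold. Among 12449 unaltered genes 10 passed. The simulated counts vary by counting error alone, without differences between cultures or a trend with GC content. The 10 therefore does not tell how many calls in the real libraries are false. The step ratio of 1.3482 was recovered, and the recovered reads were right up to a common factor for 100% of genes with a solution and exact for 84.9%. A first simulation that held only the 12649 analysed genes recovered a wrong ratio of 0.674. It held 1 gene with a single read in both libraries, against 715 in the simulation of all genes, and whether this was the cause was not tested. Of 400 random lists of 20 unaltered genes, 4.5% stood apart, a rate for genes drawn without regard to each other. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.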

Results

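The transcriptome of MDA-MB-231 cells was measured by RNA sequencing in a control culture, a culture depleted of FoxO3 and a culture depleted of both Geminin and FoxO3. FoxO3 is a forkhead transcription factor that is restrained by AKT phosphorylation. Geminin, encoded by GMNN, binds the licensing factor CDT1 and blocks relicensing of replicated DNA. Each group holds 1 library, so every difference is one between 2 libraries. The FPKM values rest on inferred totals of 14507410 reads for the control, 10760613 for the FoxO3 depletion and 12267332 for the co-depletion. At least 1 FPKM was reached by 13242 genes in the control, 12762 in the FoxO3 depletion and 12896 in the co-depletion.

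The depleted genes were low in the libraries labelled for them. FOXO3 (ENSG00000118689) stood at 12.2 FPKM in the control, 2.79 in the FoxO3 depletion and 2.94 in the co-depletion. Its level was thus 22.8% of control in the FoxO3 depletion, with a 95% counting interval of 19.3% to 26.8%, and 24.1% in the co-depletion, with an interval of 20.6% to 28.0%. GMNN (ENSG00000112312) stood at 112.3 FPKM in the control and 112.2 in the FoxO3 depletion, and at 37.0 in the co-depletion, which is 32.9% of control (29.3% to 36.9%). FOXO3 shares sequence with the pseudogene FOXO3B, so its reads are uncertain to that extent, and FOXO3B was listed at 0.61 FPKM in the control and 0.10 and 0.13 in the depleted libraries. DICER1 (ENSG00000100697), the ribonuclease that cuts microRNA precursors, was at 39.3 FPKM in the control, 14.8 in the FoxO3 depletion and 17.9 in the co-depletion. That is 37.6% of control (34.1% to 41.3%) after FoxO3 depletion and 45.6% (41.9% to 49.5%) after co-depletion. Its log2 ratios of -1.35 and -1.09 were -0.87 and -0.71 after adjustment for GC content.

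**Figure D1:**
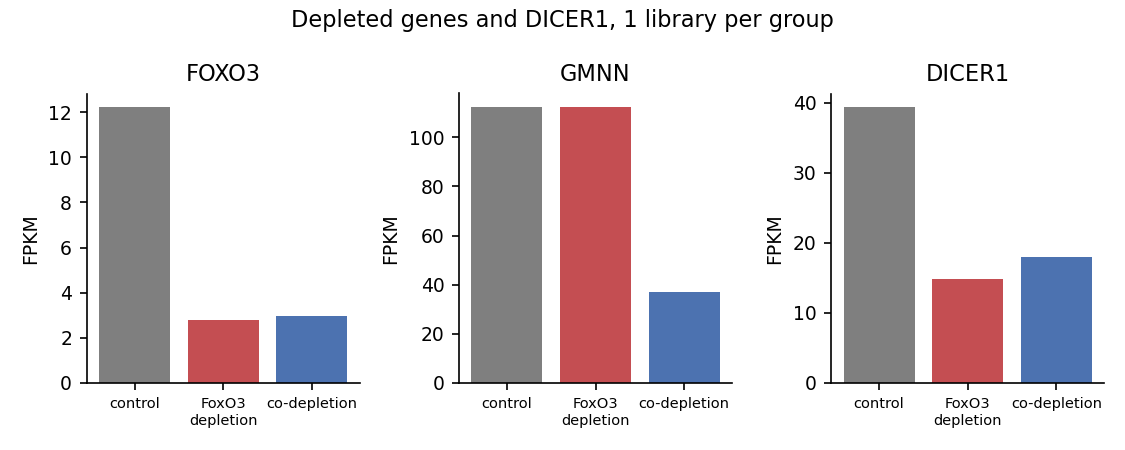
Bars give the FPKM of FOXO3, GMNN and DICER1 in the control, FoxO3-depleted and co-depleted libraries, 1 library per bar and each panel on its own axis from 0. FOXO3 and DICER1 are lower in both depleted libraries, with FOXO3 at 12.2, 2.79 and 2.94 FPKM, and GMNN is lower only in the co-depletion, at 37.0 FPKM.

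The first comparison asks how the transcriptome differs when FoxO3 is depleted. Of 18 NF-kB and inflammatory cytokine genes 13 were at least 1.5-fold higher, and of 22 DNA damage response genes 10 were lower, or 7 after GC adjustment. The highest ratio on the FPKM + 1 scale was that of SAA1, an acute-phase protein, at 207.5 FPKM against 33.0, an FPKM ratio of 6.28 (5.54 to 7.14). The cytokine IL6 was at 27.3 FPKM against 5.46 (ratio 5.0, 3.85 to 6.57) and the matrix glycoprotein THBS1 at 2368 against 559.6 (4.23, 4.15 to 4.32). Lower genes included the metallothionein MT1E, at 29.4 FPKM against 138.2, and the kinetochore protein CENPF, at 30.01 against 137.9.

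By size, 85 of 12649 genes were called higher and 661 lower. Of the called genes 88.6% were thus lower, but AT-rich transcripts made up most of these, with a median GC content of 38.6% against 48.1% for all analysed genes. After adjustment for GC content, chosen after seeing the data, 120 genes were higher and 184 lower, a share of 60.5% lower. Of the called genes, 159 of the 661 lower and 75 of the 85 higher kept their call. When the genes were divided into 10 equal bins by GC content, in the bin poorest in GC the median log2 ratio was -0.67, and 315 of 1265 genes were called lower. In the bin richest in GC the median was 0.04, with 10 called lower. Across genes, which are not independent replicates, Spearman's rho between ratio and GC content was 0.40.

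Besides the genes above, the largest ratios included the chemokine CXCL10, at 4.91 FPKM against 0.41 (ratio 11.9, 5.46 to 30.9), and the phosphatase DUSP1, at 48.8 against 12.4 (3.94, 3.49 to 4.45). Adrenomedullin (ADM) was at 103.0 FPKM against 28.3, the helix-loop-helix inhibitor ID3 at 44.1 against 12.9, PPME1 at 208.9 against 57.0 and MAMDC2 at 33.8 against 8.67. Among the lowest ratios were HSD17B12, at 20.8 FPKM against 95.4, FAM111B at 6.21 against 29.8, FRYL at 8.03 against 36.4, UACA at 22.2 against 88.9, the splicing regulator MBNL1 at 17.8 against 70.3 and SVIP at 8.93 against 36.2. After GC adjustment the log2 ratios of HSD17B12, FAM111B and SVIP moved from -2.15, -2.09 and -1.90 to -1.55, -1.43 and -1.18, and that of CXCL10 from 2.07 to 2.72.

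Of the 36 fixed lists with a percentile, 10 stood above and 2 below the random lists. In the list of NF-kB and inflammatory cytokine genes, 13 of 18 measured members were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 0.77 at percentile 100 of the random lists. IL11 was at 166.8 FPKM against 57.0 and the growth factor CSF2 at 11.99 against 3.96. Of 19 YAP/TEAD targets, 8 were higher, or 7 after GC adjustment, and 3 lower (median 0.45, percentile 100), among them F3, the initiator of coagulation, at 737.8 against 234.6 FPKM, ANKRD1 at 555.9 against 179.7 and CYR61 at 1304 against 482.0. RBMS3 of the same list was lower, at 5.67 against 15.7, with a log2 ratio of -1.33, or -0.64 after GC adjustment. Immediate early genes were higher in 4 of 12 and lower in 0 (median 0.54, percentile 100), with ATF3 at 18.9 against 6.84 and JUNB at 26.3 against 13.3 FPKM. TGF-beta targets were higher in 4 of 14 and lower in 1 (median 0.29, percentile 99.8). With a minimum mean of 5 FPKM the TGF-beta median was 0.15, at percentile 92.7.

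Genes of the integrated stress response were higher in 6 of 17, or 5 after GC adjustment, and lower in 0 (median 0.39, percentile 100), led by the amino acid transporter subunits SLC7A5, at 253.8 against 115.2 FPKM, and SLC3A2, at 285.4 against 145.0. Ribosome biogenesis genes (median 0.39, percentile 100), proteasome subunits (0.35, percentile 99.97), histone genes (0.31, percentile 99.7) and ribosomal proteins (0.28, percentile 99.1) stood above the random lists with few members past 1.5-fold. The numbers past it upward were 2 of 20, 1 of 28, 1 of 13 and 0 of 46. After GC adjustment the ribosomal protein median lay at percentile 92.9, and 5 proteasome genes passed 1.5-fold. Luminal breast markers were higher in 2 of 7 and lower in 1 (median 0.43, percentile 99.9), through the keratins KRT8, at 1105 against 705.0 FPKM, and KRT18, at 202.1 against 117.9, while ESR1, the oestrogen receptor gene, stayed under 1 FPKM in all 3 libraries, at 0.04, 0.12 and 0.08. With no minimum on FPKM the luminal median was 0.10, at percentile 93.3.

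The DNA damage response list had the lowest median, with 10 of 22 members lower, 0 higher and a median of -0.48 at percentile 0.15. The checkpoint kinases ATM and ATR were at 17.7 against 50.7 FPKM and 5.64 against 18.0, BRCA1 at 4.92 against 17.4 and the helicase BRIP1 at 9.68 against 29.3. After GC adjustment the median was -0.36, with 7 members lower, and the log2 ratio of BRIP1 went from -1.50 to -0.85. The 13 mitochondrially encoded transcripts had a median of -0.26 (percentile 0.06) with 0 past 1.5-fold, and their share of all FPKM was 4.22% in the control and 3.49% in the FoxO3 depletion.

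Genes that FoxO factors are known to activate did not stand apart as a list. Of 25 measured, 3 were higher and 4 lower (median -0.06, percentile 38.0). YPEL3, SESN3 and SESN1 were lower, at 3.69 against 11.6, 2.12 against 7.26 and 2.48 against 6.60 FPKM, and GADD45A was higher, at 111.6 against 55.9. After GC adjustment the log2 ratio of SESN3 went from -1.40 to -0.73. Within the FOXO family, FOXO3 and FOXO4 passed 1.5-fold downward and 0 genes upward, with FOXO4 at 2.52 against 8.11 FPKM, FOXO1 at 2.86 against 3.59 and FOXO6 at 2.98 against 1.78. Of 15 microRNA processing and effector genes, DICER1 alone passed 1.5-fold (median -0.05, percentile 45.5). G2/M and mitosis genes were lower in 9 of 26 and higher in 0, with CENPE at 9.31 against 27.2 and TOP2A at 175.4 against 477.7 FPKM, but the list median was -0.05 (percentile 6.94), and after GC adjustment 6 were lower and CENPE's log2 ratio went from -1.45 to -0.76. Replication licensing genes had a median of -0.15 (percentile 10.3) and genes of G1/S and DNA synthesis -0.11 (percentile 7.63).

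The other lists lay within the random range in this comparison. Their medians were -0.03 for p53 targets, 0.06 for the BCL2 family and IAPs, -0.01 for mesenchymal genes, -0.05 for epithelial genes, -0.16 for matrix proteases and inhibitors, 0.11 for MDA-MB-231 metastasis genes, 0.09 for stem and basal markers and 0.10 for the type I interferon response. ER chaperones had 0.23, heat shock genes -0.03, cholesterol synthesis 0.01, hypoxia genes 0.12, glycolysis 0.04, the nuclear-encoded respiratory chain 0.11 and autophagy and lysosome genes -0.17. NRF2 and antioxidant genes had 0.22, receptor tyrosine kinases and insulin signalling -0.16, deacetylases and corepressors -0.01 and nuclear-retained long RNAs 0.01. GC adjustment placed 3 of these above the random lists, the metastasis genes (0.40, percentile 100), the interferon genes (0.20, percentile 99.6) and the NRF2 genes (0.29, percentile 98.7). It placed 2 below them, the matrix proteases (-0.22, percentile 0.09) and glycolysis (-0.00, percentile 2.31). Alternatives fixed beforehand also moved some. With no minimum on FPKM the metastasis genes lay at percentile 98.4 and the interferon genes at 99.505. With a mean of at least 5 FPKM the metastasis genes lay at 99.37 and the matrix proteases at 1.975, and after rescaling to TPM the interferon genes at 99.59.

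Markers of other cells gave no uniform shift. Of 11 leukocyte markers 4 had a mean of at least 1 FPKM, 2 of these were lower, or 1 after GC adjustment, and 0 higher, and LAPTM5 was at 66.5 FPKM in the control, 59.3 in the FoxO3 depletion and 56.9 in the co-depletion. Fibroblast markers COL1A1 and PDGFRB were higher, at 25.3 against 13.4 and 15.0 against 6.24 FPKM, while COL3A1 was at 0.13 against 0.16. Of the endothelial markers KDR reached 1 FPKM, at 6.97 against 5.44. Of HEK293, a common lentivirus packaging line, 4 markers were listed and 0 had a mean of 1 FPKM, and their summed FPKM was 0.03 in the control and 0.02 in the FoxO3 depletion.

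**Figure D2:**
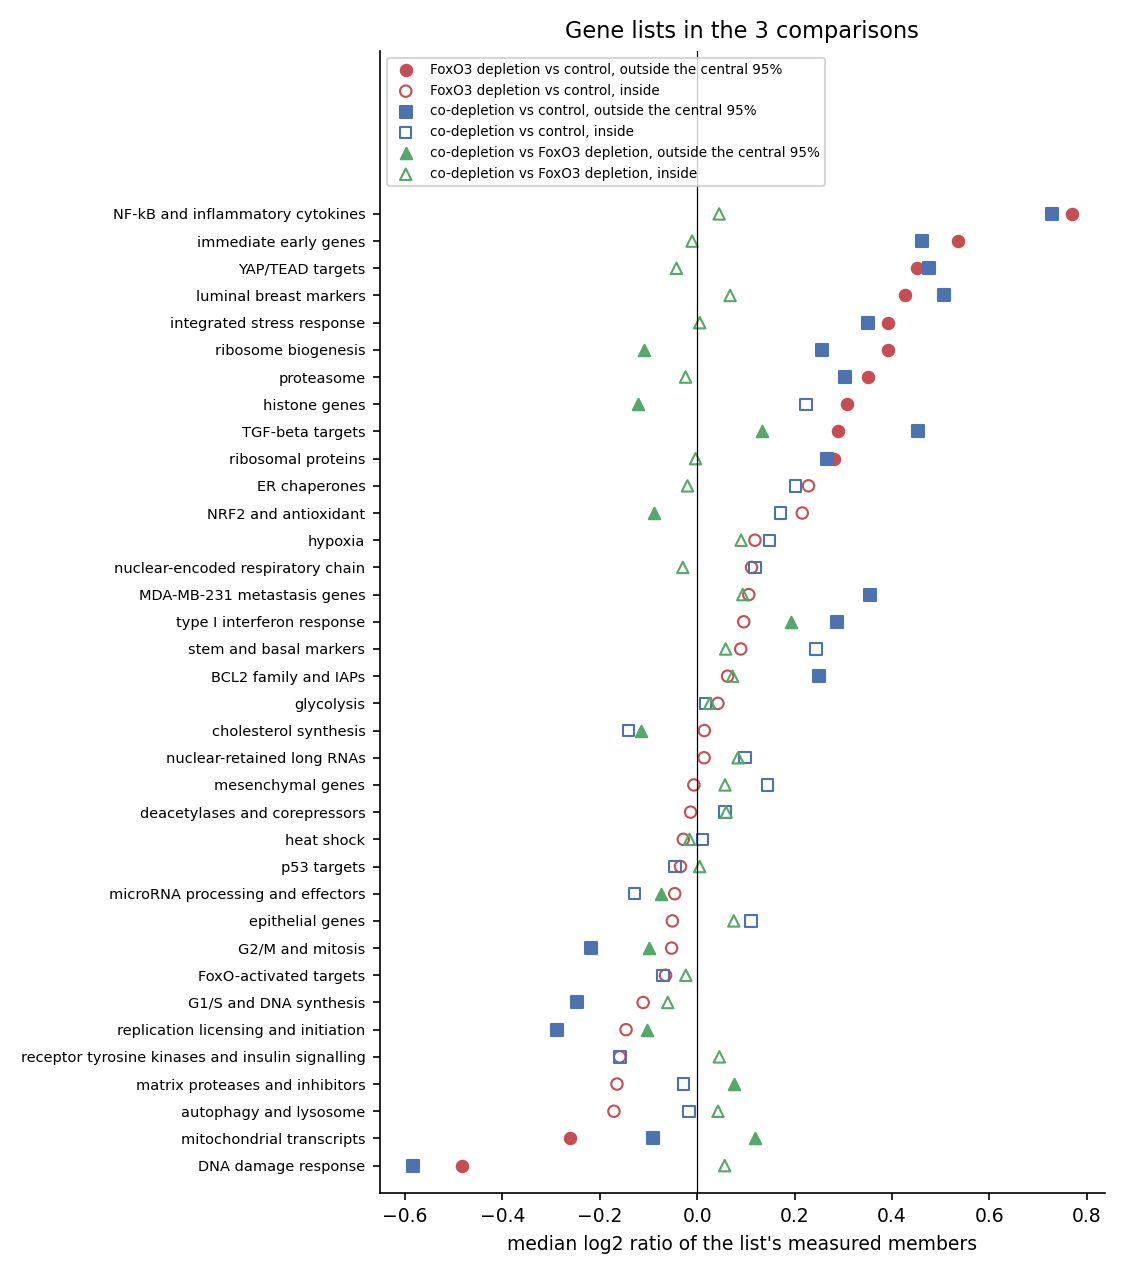
Points give the median log2 ratio of each fixed gene list in the 3 comparisons, filled where it lies outside the central 95% of expression-matched random lists and open where it lies inside. NF-kB genes stand highest in both comparisons with the control, at 0.77 and 0.73, and DNA damage response genes lowest, at -0.48 and -0.58.

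**Figure D3:**
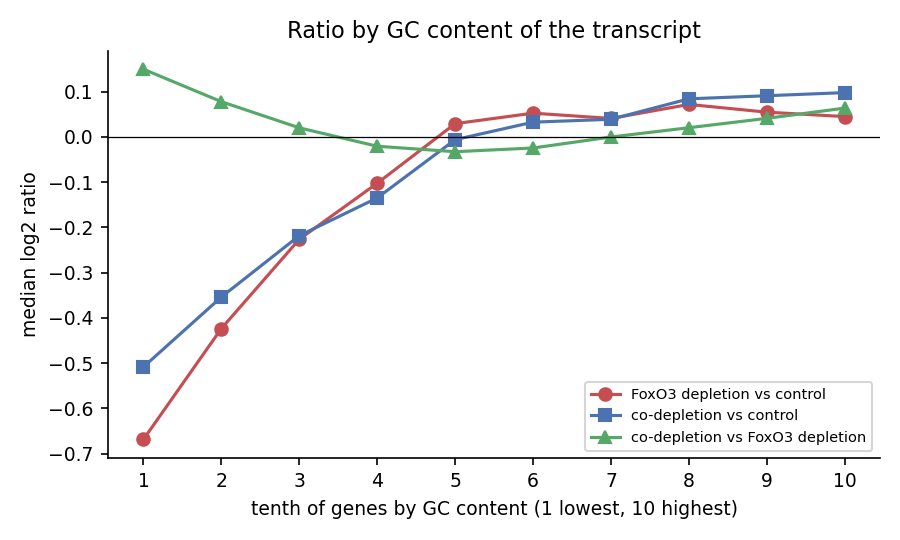
Lines join the median log2 ratio of genes in 10 equal bins of transcript GC content for the 3 comparisons, bin 1 being poorest in GC. Both comparisons with the control start low, at -0.67 and -0.51, and end at 0.04 and 0.10, while the co-depletion set against the FoxO3 depletion starts at 0.15.

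The second comparison asks how cells depleted of both Geminin and FoxO3 differ from control cells. Of the fixed lists, NF-kB and inflammatory cytokine genes had the highest median and DNA damage response genes the lowest. CXCL10 was at 8.27 FPKM against 0.41 (ratio 20.1, 9.46 to 51.1), SAA1 at 187.3 against 33.0 (5.67, 5.0 to 6.45) and IL6 at 25.8 against 5.46 (4.71, 3.64 to 6.18). MT1E was at 29.5 FPKM against 138.2 and CENPF at 36.4 against 137.9. Interferon-response genes stood above the random lists in this comparison and lists of cell-cycle genes below them.

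By size, 79 genes were called higher and 285 lower, which is 78.3% lower. After GC adjustment 99 were higher and 103 lower, or 51.0% lower, and 91 of the 285 lower and 70 of the 79 higher genes kept their call. Across genes, Spearman's rho between ratio and GC content was 0.44. High ratios included ID3, at 48.7 FPKM against 12.9, THBS1 at 1855 against 559.6, SAA2 at 10.5 against 2.59, ADM at 87.0 against 28.3, INAVA at 7.75 against 1.95 and DUSP1 at 38.8 against 12.4. SAA1 and SAA2 are near-identical copies, so the division of reads between them is uncertain. Low ratios included HSD17B12, at 26.4 FPKM against 95.4, the mitochondrial ribosomal protein MRPL10 at 7.5 against 28.3, FAM111B at 7.97 against 29.8, MBNL1 at 20.3 against 70.3 and the growth factor FGF5 at 5.29 against 19.6.

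Of 36 lists, 12 stood above the random lists and 5 below. NF-kB and inflammatory cytokine genes were higher in 12 of 18 and lower in 0 (median 0.73, percentile 100), with BIRC3 at 53.3 FPKM against 23.4. YAP/TEAD targets were higher in 6 of 19 and lower in 4, or in 2 after GC adjustment (0.48, percentile 100, and 0.37, percentile 99.95), TGF-beta targets higher in 6 of 14 and lower in 1 (0.45, percentile 100), immediate early genes higher in 4 of 12 (0.46, percentile 100) and integrated stress response genes higher in 4 of 17 (0.35, percentile 100). Type I interferon response genes were higher in 7 of 32 and lower in 0 (0.29, percentile 100). Among them OASL was at 129.9 FPKM against 65.6, IFIT1 at 134.2 against 79.9 and OAS1 at 10.8 against 5.93. MDA-MB-231 metastasis genes, a list known from selection of this line in mice, were higher in 4 of 16 and lower in 3 (0.36, percentile 99.99), and after GC adjustment higher in 7 (0.54, percentile 100). IL11 and CXCL1, which are also members of the NF-kB list, were at 141.3 against 57.0 and 9.36 against 3.55 FPKM. MMP1 was lower, at 16.4 against 32.0.

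Luminal breast markers (0.51, percentile 99.98), proteasome subunits (0.30, percentile 100), ribosomal proteins (0.27, percentile 99.6) and ribosome biogenesis genes (0.26, percentile 99.3) also stood above the random lists. Adjusted for GC and length, ribosomal proteins lay within the range (percentile 96.9). The BCL2 family and IAPs stood above the random lists at 0.25 (percentile 99.7), but within the range after GC adjustment, at 0.20 (percentile 96.3), and with a minimum mean of 5 FPKM (percentile 93.8). DNA damage response genes were lower in 11 of 22 and higher in 0 (-0.58, percentile 0.00), or in 5 after GC adjustment (-0.44, percentile 0.00), with BRCA1 at 5.43 FPKM against 17.4 and BRCA2 at 3.45 against 8.71. Replication licensing and initiation genes were lower in 5 of 23 (-0.29, percentile 0.24), or in 2 after GC adjustment (-0.17, percentile 0.34), with the GINS subunits GINS3 at 6.08 against 13.2 and GINS4 at 26.7 against 41.8. G1/S and DNA synthesis genes were lower in 1 of 23 (-0.25, percentile 0.32), that gene being POLA1, the catalytic subunit of polymerase alpha, at 14.8 against 31.7. G2/M and mitosis genes were lower in 9 of 26 (-0.22, percentile 0.11), or in 3 after GC adjustment (-0.13, percentile 0.12), with TOP2A at 213.3 against 477.7 and KIF11 at 22.0 against 41.2. Mitochondrial transcripts had -0.09 (percentile 1.32), and -0.01 (percentile 5.05) after GC adjustment.

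Genes activated by FoxO factors again lay within the random range, at -0.07 (percentile 31.4), with RBL2 at 6.49 FPKM against 14.6. ZEB1, a repressor of epithelial genes, was at 11.2 against 31.3, although the mesenchymal list as a whole was at 0.14 (percentile 91.4), with the collagen COL5A1 at 258.8 against 132.4.

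Both comparisons with the control called 280 genes in the same direction, 56 higher and 224 lower. Simulated exchangeable libraries sharing 1 control gave 26.5 such genes on average (16 to 36), and independent lists of the observed sizes would give 15.4. The simulation called only 188.4 and 190.3 genes per comparison, against 746 and 364 observed, so its overlap is not that of lists of the observed sizes. After GC adjustment 142 were shared, 74 higher and 68 lower, so shared lower genes no longer outnumbered shared higher ones. The correlation of log2 ratios across genes was 0.89 against 0.50 in the simulation, and the covariance 0.18 against 0.08. With 1 control library it could not be split, and part of the excess may come from that library. Shared higher genes were led by SAA1, CXCL10, IL6, THBS1, ID3, ADM, DUSP1 and F3, and shared lower genes by MT1E, CENPF, HSD17B12, MRPL10, FAM111B, FOXO3, MBNL1 and SVIP.

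The third comparison asks what Geminin depletion adds to FoxO3 depletion. Among genes with a mean of at least 5 FPKM, GMNN had the largest difference, at 37.0 FPKM against 112.2, or 33.0% (29.2% to 37.1%). FOXO3 was at 106% of its FoxO3-depleted level (85.8% to 130%) and DICER1 at 121% (109% to 135%). The Geminin partner CDT1 was at 22.5 FPKM against 34.7, lower by a ratio of 1.54 (1.35 to 1.75), and 2 of 32 interferon-response genes passed 1.5-fold upward and 0 downward, among them OAS1 at 10.8 against 6.04 (1.79, 1.33 to 2.43).

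The depleted libraries lay close to each other, with a standard deviation of log2 ratios of 0.21 across genes, against 0.48 and 0.42 for the comparisons with the control. By size 16 genes were higher and 8 lower, of which 2 and 2 were protein-coding. With at least 20 recovered reads, 6 were higher and 2 lower. Most of those called were noncoding RNAs and pseudogenes counted from few reads, such as AC092683.1, at 3.90 FPKM against 0.78 (5.01, 2.22 to 13.3), and LINC01088, at 3.87 against 1.30 (2.98, 1.44 to 6.77).

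Of 36 lists, 4 stood above and 7 below the random lists, each by a small median. Interferon-response genes were higher in 2 of 32 (0.19, percentile 100), namely OAS1 and SAMD9, the latter at 9.44 FPKM against 5.52. In the control OAS1 was at 5.93 FPKM and SAMD9 at 14.4, so SAMD9 stayed under its control level. Against the control, 2 of the 32 were higher and 3 lower after FoxO3 depletion, and 7 higher and 0 lower after co-depletion. TGF-beta targets had 0.13 (percentile 98.9) and mitochondrial transcripts 0.12 (percentile 99.98), each with 0 past 1.5-fold. Matrix proteases and inhibitors had 0.08 at percentile 97.6, and lay inside the range after GC adjustment (percentile 97.4) and with pseudocounts of 0.1 (97.3) and 0.5 (97.4), no minimum (94.3), median-ratio scaling (97.3) and TPM (97.1). Replication licensing genes were lower in 2 of 23 (-0.10, percentile 0.07), namely CDT1 and GINS3. After GC adjustment CDT1 alone passed 1.5-fold, as the log2 ratio of GINS3, close to that limit, went from -0.59 to -0.56. Histone genes had -0.12 (percentile 0.35), cholesterol synthesis -0.12 (percentile 0.04), with INSIG1 at 37.0 against 52.4, ribosome biogenesis -0.11 (percentile 0.02), G2/M and mitosis -0.10 (percentile 0.02) and NRF2 genes -0.09 (percentile 0.11). MicroRNA genes had -0.07 (percentile 2.08), and after GC adjustment -0.07 at percentile 7.04. Just inside the range were G1/S and DNA synthesis genes (-0.06, percentile 2.69) and hypoxia genes (0.09, percentile 97.465). The G1/S genes lay below it with a pseudocount of 0.1 (2.385), a mean of at least 5 FPKM (1.17) and GC adjustment (0.735). Hypoxia genes lay above it with a mean of at least 5 FPKM (98.28), median-ratio scaling (97.58) and TPM (97.755), and inside it after GC adjustment (93.8).

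By the size rule 9 genes called in the FoxO3 depletion were moved back in the co-depletion. This count rests on low genes, being 77 and 31 with pseudocounts of 0.1 and 0.5, 16 with no minimum, 22 after rescaling to TPM, 0 with a mean of at least 5 FPKM and 2 with at least 20 recovered reads. The simulated exchangeable libraries gave 26.0 such genes on average (15 to 40). They have the same spread in every library, whereas the real depleted libraries lay closer to each other than to the control. The standard deviation of log2 ratios was 0.21 between them, against 0.48 and 0.42 for the comparisons with the control. The simulation therefore cannot decide whether 9 is more or fewer than random differences would give. Of the 9 genes 1, IL7, was protein-coding, at 3.73 FPKM in the control, 1.26 in the FoxO3 depletion and 3.58 in the co-depletion. IL7 was named after its values were seen.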

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

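No paired analysis was possible because each group has 1 library. The adjustments for GC and the minimum of recovered reads were chosen after seeing the data. Counts are given as higher and lower genes for FoxO3 depletion against control, co-depletion against control and co-depletion against FoxO3 depletion, then genes shared by both depletions and genes moved back. A pseudocount of 0.1 gave 166 and 1049, 144 and 551, 100 and 56, 527 shared and 77 moved back, and one of 0.5 gave 49 and 28 in the third comparison and 31 moved back. A mean of at least 5 FPKM gave 1 and 1 there with 0 moved back, and no minimum gave 28 and 27 with 16. Protein-coding genes alone gave 2 and 2 with 1 moved back. Rescaling to TPM gave 434 lower in the second comparison, 43 and 32 in the third and 22 moved back. The 3-fold rule gave 12 and 50, 9 and 17, 0 and 2, 20 shared and 1 moved back, and the 1.5-fold rule 506 and 2112, 509 and 1550, 171 and 78, 1672 and 123. GC adjustment left 184 and 103 lower genes in the first 2 comparisons and 142 shared, and GC and length adjustment 178, 102 and 137. At least 20 recovered reads left 6 and 2 in the third comparison and 2 moved back. The thresholds and minimums change the counts by construction. Rescaling to TPM scales every library up, from FPKM sums of 701474, 719031 and 719248, so the fixed pseudocount and minimum weigh less. The genes analysed rose from 12649 to 13317. How much of the change in counts comes from this was not tested. Lower genes outnumbered higher ones in both comparisons with the control under every setting listed, rescaling by the median ratio included, which gave 82.8% and 70.9% lower. For co-depletion against control the margin was small after GC adjustment, at 103 lower and 99 higher. With GC and length adjustment it was 102 lower and 98 higher. The median ratio of all genes, -0.07 in the first comparison, was -0.11 after rescaling to TPM. Of 108 list medians, GC adjustment ended the standing of 5 and gave it to 8, and no list that stood apart without it changed sign. Of the 8, glycolysis did change sign in both comparisons with the control, from 0.04 to -0.00 and from 0.02 to -0.02. The counting intervals limit what low genes can show, and no setting replaces a second culture.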

Other observations

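Metallothioneins, small proteins that bind zinc and copper, were chosen as a group after their values were seen. Of 12 protein-coding members in the files, 3 had a mean of at least 1 FPKM, and these were at least 1.5-fold lower than control in both depletions. MT2A was at 740.8 FPKM in the control, 365.3 in the FoxO3 depletion and 340.7 in the co-depletion, MT1E at 138.2, 29.4 and 29.5, and MT1A at 9.40, 5.40 and 4.94. The zinc exporter SLC30A1, a target of the same zinc-sensing factor, was at 12.6, 3.92 and 4.93, and that factor, MTF1, at 8.68, 4.74 and 5.02. No GC-adjusted ratio is given for the metallothioneins, SLC30A1 or MTF1. How far the trend with GC content carries their lower levels is therefore not shown. The metallothionein genes resemble each other closely, so their reads are uncertain.

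The tests of GC content on the share of lower genes and on the NF-kB list, and those of depth, leukocytes and fibroblasts, were set after the results were seen, bounds included. The first pattern is the excess of lower genes against the control. Depth is argued against as its cause, since among 264 called genes with a mean of at least 500 recovered reads over the 3 libraries 87.5% were lower, where 60% or less was set for depth as the cause. Adjustment for GC content took the lower share from 88.6% to 60.5% after FoxO3 depletion, just above the 40% to 60% set for GC as the whole cause, and from 78.3% to 51.0% after co-depletion, inside it, while 20 shuffles of GC content among genes, which centre the ratios alike, left 81.9% and 68.5% on average. A trend with GC content may thus carry much of the excess, but the adjustment removes it whether it arose in the libraries or in the cells. Length alone left 78.5% lower, between its bounds, and an effect of FoxO3 depletion on AT-rich transcripts cannot be told apart from a difference of the single control library.

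The second pattern is the higher NF-kB and inflammatory cytokine list. The GC trend is argued against as its cause, because the median log2 ratio was 0.77 before adjustment and 0.80 after. Of 7 leukocyte markers under 1 FPKM in the control, the highest in the FoxO3-depleted library, TYROBP, was at 0.17 FPKM, while the summed FPKM of the list was 717.2 against 408.1, which argues against leukocytes. The fibroblast markers COL1A1 and PDGFRB, which the control also carries, were higher, at 25.3 against 13.4 and 15.0 against 6.24 FPKM. Of 5 others under 1 FPKM in the control, DCN and LUM among them, 0 were higher. The highest of the 5, COL3A1, was at 0.13 against 0.16. These values argue against a share of fibroblasts large enough to raise those 5 markers, but the level that a share would bring was not measured. A response to FoxO3 depletion and a difference in infection, density or handling of the cultures both stay open, untested.

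The third pattern is the lower DICER1. Its log2 ratio was set among those of its 200 nearest genes in GC content, length and expression, a test written before its result. It lay at percentile 6.0 after FoxO3 depletion, where those genes had a median of -0.57, and at percentile 4.5 after co-depletion, where they had -0.48. The first value lies within the range that similar transcripts show, and the second lies between the bounds set. The percentiles of 6.0 and 4.5 lie close together, so the comparisons are not read as differing. After FoxO3 depletion DICER1's log2 ratio was -1.35, lower than the median of -0.57 of the similar genes. A general shift of such transcripts may therefore carry part of the drop. The test does not decide whether a specific effect on DICER1 adds to it, and such an effect stays open.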
